A study of Mus musculus with 4 samples.

How the data were processed

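RNA was measured in 4 libraries of mouse endometrial cancer cell lines, 2 of the line named MECPK and 2 of the line named MSH2KO21B. Per the labels' protocols, total RNA was extracted with a column kit and made into libraries by standard Illumina steps. The strand setting, read length and sequencing depth are not given in the sources used here.

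The table deposited by the authors holds TPM, a unit of relative abundance in which each transcript's estimated reads are divided by its length and scaled to a sum of 1000000 in each library. Per the submitters' processing notes, kallisto 0.43.1 and the mouse build GRCm38 were used. The transcript set and the options are not given in the sources used here. All 4 columns had that sum, so every value is a share of its own library. TPM keeps no depth, so the depth of each library is unknown, and no counting interval or detection limit was computed. A gene listed at 0 could therefore not be separated from a gene below the reach of the sequencing.

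The table lists 61440 Ensembl transcripts without gene names. Transcripts were paired with genes through the GENCODE M21 annotation of GRCm38 by their identifier without its version, and 60503 matched, 56128 of them in the same version. The 937 transcripts that did not match held between 0.733% and 0.944% of a library's TPM and were left out of the gene values. TPM values were then summed over the transcripts of each gene, which gave 22594 genes, 21830 of them protein-coding. The matched transcripts were nearly all of coding type, so noncoding genes such as Xist, H19 and Meg3 were not analysed here. Kallisto shares reads among similar transcripts by estimation, so values of genes with near-identical copies are uncertain. Among those named here, this holds for the histone, glutathione transferase, H2-Q and keratin families and for ribosomal protein genes, which have many pseudogenes.

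Libraries were grouped by line from their titles. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No transcript had the same non-zero value in both MECPK libraries, out of 28999 above 0 in both, and 1 of 30991 did in MSH2KO21B, so no library was treated as a copy of another.

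The only comparison that the design names is between the 2 lines, and every difference is MSH2KO21B minus MECPK. Genes with at least 1 TPM in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(TPM + 1), with the line as the only term. The adjustment was Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. The fit had 2 residual degrees of freedom and 2.49 prior degrees of freedom. Gene lists with at least 5 tested members were compared with all other genes by limma's camera, with its preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 27 lists tested.

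The samples, the test, the threshold, the alternatives, the rule for named genes and 31 gene lists were fixed before the data were examined. The lists covered mismatch repair, homologous recombination and Fanconi anaemia, p53 targets, nucleic acid sensing, interferon-stimulated genes, MHC class I antigen presentation, MHC class II, immune checkpoint and costimulation, chemokines and cytokines, epithelial genes, mesenchymal genes, Mullerian and uterine genes, HOX genes, RAS-MAPK output, PI3K and FOXO, cell cycle, CDK inhibitors and senescence, Wnt targets, TGF-beta targets, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and integrated stress response, NRF2 targets, germline genes, imprinted genes, immune cell markers, endothelial markers, X and Y identity, mitochondrially encoded genes, replication-dependent histones and cytosolic ribosomal proteins. The rule for named genes took Msh3, Msh6, Pms2 and Trp53. It then took the 12 genes with the largest difference in each direction among genes past the threshold with at least 10 TPM in the higher line and no overlap between the lines, leaving out unnamed gene models. It also took up to 4 members per list with the largest differences past the threshold. Some genes that these rules took are not reported here. The pairing of transcripts with genes was planned from the table itself and had to come from the annotation instead.

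Settings varied were limma without the trend, quantile normalization, no filter on low values, a filter of 10 TPM, a pseudocount of 0.1, a block for the replicate number, each library left out in turn, limma's treat against a log2 fold change of 1, camera with an estimated correlation, and fry in place of camera. Median-ratio scaling, rescaling without the mitochondrially encoded genes and summing protein-coding transcripts only were added after seeing the data. Camera with an estimated correlation rests on the 2 residual degrees of freedom, so with 2 libraries per line it had little power to call a list. Count-based tests and normalizations were not run, because the values are TPM.

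The fit was tested on simulated data made from the MECPK means, with low values raised to a floor, and the spread of the 11921 genes tested. It had 2 libraries per line. Far fewer genes were changed in it than the 9088 called in the data, so its recovery shares do not give the power of this comparison. The fit recovered 32 of 67 genes changed by 1.5-fold (47.8%), 41 of 67 changed by 2-fold (61.2%) and 59 of 66 changed by 4-fold (89.4%), with 5 false calls among 11721 unchanged genes. No gene was called when none was changed. In a further simulation, camera called 10 of 10 shifted lists and 0 of 40 unshifted lists. Its genes varied independently and none outside the shifted lists changed, so it does not show how often lists of correlated genes are called falsely. In the data the estimated correlation was 0.82 for mitochondrially encoded genes and 0.81 for cytosolic ribosomal protein genes. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.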

Results

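Steady-state RNA was profiled in 2 mouse endometrial cancer cell lines, each run in duplicate. The MECPK line and the MSH2KO21B line each gave 2 libraries, called replicates 1 and 2 here. The labels do not say how the lines were made or whether either derives from the other, and the names are used only as labels. Between 32440 and 34959 transcripts had a value above 0 per library. At 1 TPM or more, 10822 and 10775 genes were present in the MECPK libraries and 11442 and 11478 in the MSH2KO21B libraries. The 10 most abundant genes held 11.3% and 11.1% of all TPM in MECPK and 7.27% and 7.38% in MSH2KO21B. Across the genes tested, log2 values of replicates correlated with r = 0.995 in MECPK and 0.996 in MSH2KO21B, against 0.781 to 0.783 between lines. Genes are not independent replicates, so these coefficients only describe the libraries. The median gene differed by 0.10 on the log2 scale between MECPK replicates, by 0.07 between MSH2KO21B replicates and by 0.60 between the lines.

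Of the named DNA mismatch repair genes, Msh6 was lower in MSH2KO21B (31.3 ± 2.01 against 21.1 ± 0.08 TPM, SD, n = 2), and Msh3 (log2 difference 0.68) and Pms2 (0.36) were higher. The Pms2 call was lost without MECPK replicate 1 (0.0525) or MSH2KO21B replicate 2 (0.0907) and after quantile normalization (0.385).

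Keratins were among the largest differences between the lines. MSH2KO21B was rich in keratins of the basal and stratified type. Krt5 (ENSMUSG00000061527.7, chromosome 15, 101707070 to 101712898) was at 3849 ± 54.8 TPM against 0.89 ± 0.29 TPM in MECPK (SD, n = 2). Krt14 was at 3318 ± 3.14 against 1.87 ± 0.02 TPM, Krt17 at 3273 ± 54.1 against 0.82 ± 0.07 TPM, and Krt6a at 2098 ± 97.2 against 0.56 ± 0.24 TPM. MECPK instead held keratins of simple, glandular epithelium. Krt18 (ENSMUSG00000023043.7, chromosome 15, 102028180 to 102032027) was at 1286 ± 2.91 TPM against 3.50 ± 0.94 TPM in MSH2KO21B, and Krt7 at 1252 ± 74.2 against 5.40 ± 0.63 TPM. Krt5 and Krt6a lie on chromosome 15 with Krt7 and Krt18 and moved in the opposite direction to them, while Krt14 and Krt17 lie on chromosome 11. Krt90, the stratified epithelial lectin gene Lgals7 and the keratinocyte differentiation gene Krtdap were also among the 12 genes with the largest positive differences. The others were Igfbp2, which binds insulin-like growth factors, the LIM protein gene Crip1, the chemokine gene Cxcl14, Tppp3 and the metalloproteinase inhibitor gene Timp3. Log2 differences of the 12 ran from 9.34 for Timp3 to 11.002 for Krt5.

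On the other side, the tight junction gene Cldn6 fell from 437 ± 0.87 TPM in MECPK to 0.10 ± 0.06 TPM in MSH2KO21B, and Msln, which encodes the surface protein mesothelin, from 182 ± 8.52 to 0.35 ± 0.14 TPM. The remaining genes of this group were Ankrd1 (log2 difference -8.28), the water channel gene Aqp8 (-7.47), Rgs16 (-7.31), Plscr2 (-7.18), Mal2 (-6.81), Il5ra (-6.68) and Bcl2l15 (-6.67). Eno1b had the largest negative value (864 against 0.86 TPM, log2 difference -8.87). It is a near-copy of Eno1, which had 2056 ± 102 TPM in MECPK and 2302 ± 45.5 TPM in MSH2KO21B, so its value is uncertain. All 24 genes were called by limma with Benjamini-Hochberg adjusted p from 2.3e-06 (Krt17) to 1.2e-05 (Plscr2). Of all genes tested, 88.9% had both MSH2KO21B libraries on the same side of both MECPK libraries, which chance gives for 33.3% of genes in a design of 2 against 2. So did the 135 named genes, which were chosen partly for it.

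**Figure D1:**
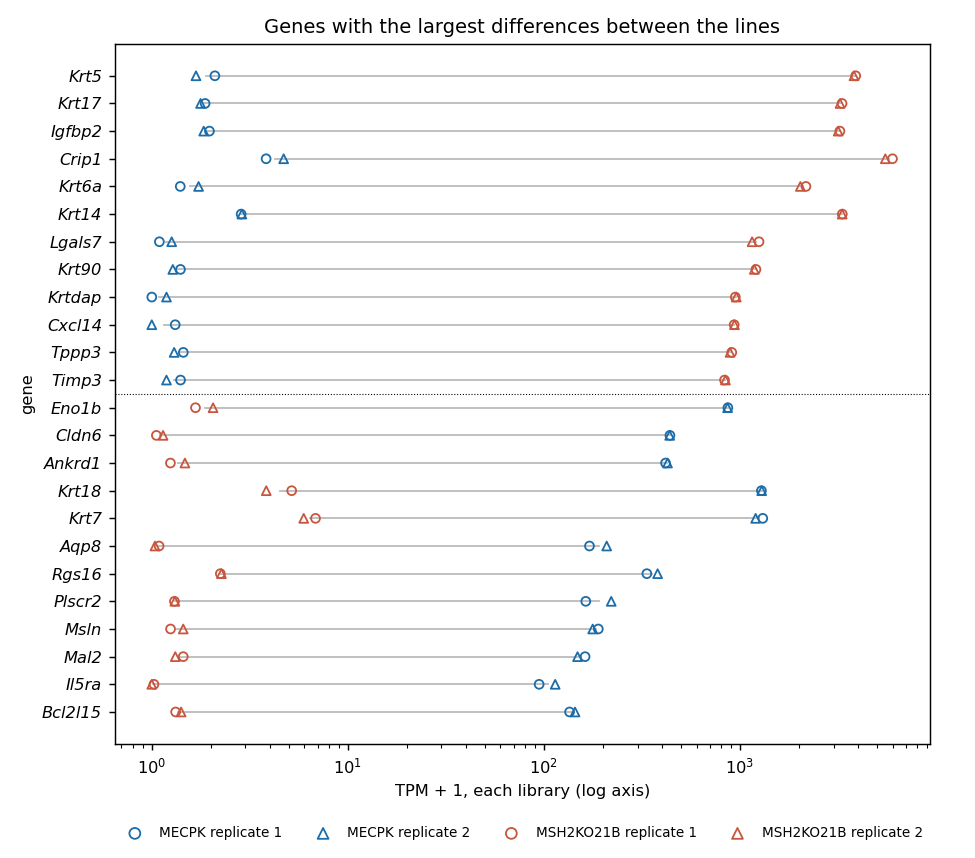
Levels of the 12 genes with the largest positive and the 12 with the largest negative difference (genes on the vertical axis, TPM + 1 per library on a logarithmic horizontal axis). Circles and triangles are replicates 1 and 2, blue for MECPK and red for MSH2KO21B, and grey lines join the means. Krt5 sits near 1 in MECPK and at 3849 TPM in MSH2KO21B, while Krt18 sits at 1286 TPM in MECPK and 3.50 TPM in MSH2KO21B.

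The difference extended across the transcriptome. Of 11921 genes tested, 9088 were called, 5550 higher and 3538 lower in MSH2KO21B. Of the called genes, 3610 differed by over 1 on the log2 scale, 2256 higher and 1354 lower. These were 1608 higher and 1802 lower after quantile normalization, and 1939 and 1590 after median-ratio scaling. The share called higher, 61.1%, depended on the scaling: it was 48.1% after quantile normalization and 52.5% after median-ratio scaling. The median of all genes was 0.19 as deposited, -0.03 after quantile normalization and 0.05 after median-ratio scaling, so list medians are given relative to the median of all genes.

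Genes of epithelial identity split in both directions. Of 39 tested members of the epithelial list, 17 were higher and 21 lower in MSH2KO21B, and the list was not called by camera (adjusted p = 0.0738). Krt5, Krt17, Krt14 and Cldn6, given above, were its largest differences. Epcam fell from 444 ± 3.08 to 112 ± 3.07 TPM while Cdh1, which encodes E-cadherin, was at 99.9 ± 0.59 TPM in MECPK and 166 ± 1.18 TPM in MSH2KO21B. These members were chosen after their values were seen. Of 20 tested mesenchymal genes, 15 were higher and 4 lower (median relative to all genes 1.65, camera adjusted p = 0.049998, and adjusted p = 0.586 with an estimated correlation). Vim, which encodes the intermediate filament vimentin, was at 1.73 ± 0.27 TPM in MECPK and 527 ± 6.71 TPM in MSH2KO21B, and the matrix protein gene Sparc at 4.53 ± 0.59 and 410 ± 2.60 TPM. Snai2, a transcription factor also used by basal epithelial cells, was at 2.22 ± 0.58 and 191 ± 5.48 TPM. Cdh2, which encodes N-cadherin, went the other way (24.7 ± 0.44 against 0.02 ± 0.01 TPM), as did Fn1, Twist1 and Itga5, chosen after their values were seen. Other members, also chosen afterwards, differed in level. Col1a1, Col1a2, Col3a1, Dcn, Lum, Thy1 and Pdgfrb stayed under 1 TPM in all 4 libraries, whereas in MSH2KO21B Col5a1 had a mean of 26.0 TPM, Col6a1 19.2 TPM, Col6a2 11.1 TPM, Acta2 15.9 TPM, Fbn1 15.6 TPM, Mmp2 3.28 TPM and Pdgfra 1.27 TPM. These 7 genes were under 1 TPM on average in MECPK. The mesenchymal call was lost without MECPK replicate 1 (0.0686), without MECPK replicate 2 (0.0617), without MSH2KO21B replicate 1 (0.0556) and with no filter on low values (0.256). It was also lost when rescaled without the mitochondrially encoded genes (0.0566) and with protein-coding transcripts only (0.0574).

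Genes of Mullerian and uterine identity were lower as a group in MSH2KO21B, with 12 of 18 tested members lower and 5 higher (median relative to all genes -1.66, camera adjusted p = 0.0120, and adjusted p = 0.586 with an estimated correlation). Pax2, a transcription factor of the developing reproductive tract, was at 39.9 ± 1.54 TPM in MECPK and 0.13 ± 0.08 TPM in MSH2KO21B, Prom1 at 40.5 ± 6.21 and 0.04 ± 0.03 TPM, and Spp1 at 206 ± 59.6 and 11.1 ± 0.46 TPM. The secreted signal Wnt4 was the largest exception (0.21 ± 0.01 against 121 ± 5.85 TPM). Wnt5a, Esr1 and Klf5, chosen after their values were seen, were also higher. The HOX genes, which set position along the body axis, were lower in 17 of 21 tested members and higher in 3 (median relative to all genes -1.13, adjusted p = 1.5e-04, and adjusted p = 0.586 with an estimated correlation). Hoxa7 had 8.07 ± 0.89 TPM in MECPK and 0.28 ± 0.03 TPM in MSH2KO21B, and Hoxa3, Hoxd4 and Hoxd9 differed by -2.34, -1.94 and -1.79 on the log2 scale. Hoxb13 and Hoxd8, named after their values were seen, were among the higher members, and after quantile normalization 1 member was higher and 18 were lower.

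MHC class I antigen presentation was higher in MSH2KO21B. Of 23 tested members 20 were higher and none was called lower, although 3 were lower after quantile normalization and 1 after median-ratio scaling. The median relative to all genes was 1.21 (camera adjusted p = 3.2e-04, and adjusted p = 0.586 with an estimated correlation). Nlrc5, the transactivator of class I genes, was at 0.02 TPM in MECPK and 18.1 ± 0.95 TPM in MSH2KO21B. The heavy chain gene H2-Q7 was at 0.05 ± 0.07 and 46.6 ± 2.89 TPM, and H2-Q4 at 2.49 ± 0.71 and 58.8 ± 3.34 TPM. Psmb8, a subunit of the immunoproteasome, was listed at 0 in both MECPK libraries and had 33.3 ± 0.24 TPM in MSH2KO21B. The light chain gene B2m, chosen after its values were seen, had 422 ± 22.7 and 2531 ± 97.8 TPM. The members not called were Psmb10, Psme1 and Psme2. Only 3 of 12 MHC class II genes passed the filter, too few for camera, and H2-DMa, Ifi30 and H2-DMb1 were all higher (log2 differences 2.45, 1.30 and 1.25). The others, among them Ciita, Cd74, H2-Aa, H2-Ab1 and H2-Eb1, stayed under 1 TPM in all 4 libraries.

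Other immune lists were mixed and not called. Of 50 interferon-stimulated genes 23 passed the filter, 12 of them higher and 5 lower (camera adjusted p = 0.262). Ifit2 (log2 difference 3.89, with 10.4 and 19.4 TPM in the MSH2KO21B libraries), Xaf1 (3.57) and Samd9l (2.71) were higher and Oasl1 lower (-4.40). Ifit1, Ifit3, Mx1, Mx2, Oas2 and Rsad2, chosen after their values were seen, stayed under 1 TPM in all 4 libraries. Nucleic acid sensing had 8 higher and 6 lower of 17, or 5 and 7 after quantile normalization (adjusted p = 0.672). Its largest differences were all negative, in the RNA sensor Ifih1 (-1.50), the adaptors Mavs (-1.49) and Tmem173 (-1.43) and the ribonuclease subunit Rnaseh2c (-1.49). The list median was -0.07 relative to all genes. Among immune checkpoint and costimulation genes 11 were higher and 5 lower of 17 (adjusted p = 0.304), led by the NKG2D ligand gene H60c (0.24 ± 0.12 against 127 ± 0.01 TPM), Nectin1 (4.33), Nt5e (2.99) and Cd80 (2.98). Cd274, which encodes PD-L1, had 1.19 ± 0.08 and 1.22 ± 0.45 TPM and was not called. Of 26 chemokine and cytokine genes, 15 were higher and 9 lower, or 9 and 9 after quantile normalization (adjusted p = 0.788). Beside Cxcl14, Tgfb2 was higher (4.15), and the colony-stimulating factor genes Csf3 (-3.74) and Csf2 (-3.22) were lower. Only 5 of 32 immune cell markers passed the filter, 3 of them higher (adjusted p = 0.393). These 3 were low in MSH2KO21B, S100a9 at 3.94 ± 1.09 TPM, Csf1r at 3.41 ± 0.10 TPM and Coro1a at 3.18 ± 0.05 TPM. Of 15 endothelial markers 4 passed the filter, too few for camera, and all were higher, Flt1 at 10.8 ± 0.87 TPM, Egfl7 at 40.3 ± 7.24 TPM, Esam at 2.45 ± 0.64 TPM and Pecam1 at 1.23 ± 0.06 TPM in MSH2KO21B.

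Targets of the tumour suppressor p53 were lower in MSH2KO21B, in 19 of 29 tested members against 8 that were higher (median relative to all genes -1.06, camera adjusted p = 0.0019, and adjusted p = 0.586 with an estimated correlation). The stress cytokine gene Gdf15 fell from 314 ± 47.3 to 5.28 ± 0.09 TPM, Ccng1 from 322 ± 12.1 to 26.5 ± 0.62 TPM and the CDK inhibitor gene Cdkn1a from 226 ± 5.46 to 38.7 ± 3.14 TPM. The peptide transporter gene Tap1, also on the MHC class I list, was higher (log2 difference 3.07). So were Perp (2.36), Sesn1 (1.56), Gadd45a (1.30) and Xpc (1.09), named after their values were seen. Trp53 itself had 92.8 ± 5.22 and 70.8 ± 1.45 TPM (log2 difference -0.38, adjusted p = 0.0037). Of 14 CDK inhibitor and senescence genes 8 were higher and 2, Cdkn1a and Trp53, lower (adjusted p = 0.312). Among them, Cdkn2a, the locus of p16 and p19Arf, had 24.2 ± 2.52 TPM in MECPK and 235 ± 4.11 TPM in MSH2KO21B, and Igfbp7 8.20 ± 1.52 and 353 ± 12.3 TPM. Cdkn2d was higher too (2.04), a call lost without MSH2KO21B replicate 1 (0.0513) or 2 (0.0512). Cell cycle genes were higher in 31 of 44 members and lower in 7 (median relative to all genes 0.16, adjusted p = 0.0396, and adjusted p = 0.621 with an estimated correlation), led by Cdc20 (2.09), Cdc25c (1.94), Ccna2 (1.48) and Nusap1 (1.38). Their call was lost with the replicate block (0.0525) and after median-ratio scaling (0.0821). The higher members numbered 25 after quantile normalization and 23 after median-ratio scaling, with 7 lower in each.

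Genes induced by RAS-MAPK signalling were lower in 19 of 27 tested members and higher in 4 (median relative to all genes -0.99, camera adjusted p = 3.4e-04, and adjusted p = 0.621 with an estimated correlation). The phosphatase genes Dusp5 and Dusp4 fell by 3.06 and 2.06 on the log2 scale, the inhibitor gene Spry4 by 2.88 and the EGF receptor ligand gene Areg by 2.26. The higher members, named after their values were seen, were Egr1, Fos, Il11 and Ccnd1, and after quantile normalization 2 members were higher. The PI3K and FOXO list had 12 higher and 13 lower members of 30 (13 and 13 adjusted over the list alone) and was not called (adjusted p = 0.537). Its median was -0.07 relative to all genes and its mean -0.28 relative to other genes. Irs2 (3.78) and Pik3ip1 (2.55) were higher, and Txnip (-2.38) was lower.

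Wnt targets were higher in 11 of 14 tested members, with Apcdd1, named after its values were seen, the only lower member (2 were lower after quantile normalization or median-ratio scaling; median relative to all genes 0.99, camera adjusted p = 0.0274, and adjusted p = 0.621 with an estimated correlation). Axin2, a feedback inhibitor widely used as a readout of the pathway, was at 0.16 ± 0.23 TPM in MECPK and 39.4 ± 2.40 TPM in MSH2KO21B. The secreted inhibitor gene Wif1 was at 0.01 ± 0.02 and 16.99 ± 0.66 TPM, Rnf43 at 0.50 ± 0.01 and 10.6 ± 0.08 TPM and Tcf7 at 2.03 ± 0.12 and 17.9 ± 0.21 TPM. TGF-beta targets were mixed, with 10 higher and 6 lower of 19 (11 and 7 adjusted over the list alone; adjusted p = 0.649). Tgfbi (6.43) and Id3 (3.01) were higher, and Inhba (-3.74) and Ltbp2 (-2.65) lower.

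Cholesterol synthesis and uptake genes were lower in MSH2KO21B, with the lowest camera p of the 27 lists. Of 24 members 22 were lower and 1, Ebp, named after its values were seen, was higher (22 and 2 adjusted over the list alone). The median relative to all genes was -1.44 (adjusted p = 3.3e-07, and adjusted p = 0.621 with an estimated correlation). Msmo1 fell from 285 ± 3.24 to 43.5 ± 1.78 TPM and Fdft1, the gene of squalene synthase, from 115.5 ± 8.92 to 18.8 ± 0.32 TPM. Tm7sf2 fell from 22.9 ± 5.30 to 2.81 ± 0.46 TPM. Hypoxia and glycolysis genes were higher in 22 of 32 tested members and lower in 6 (23 and 6 adjusted over the list alone) but were not called (adjusted p = 0.0610). The lactate exporter gene Slc16a3 was at 0.09 ± 0.04 and 92.3 ± 0.43 TPM, Bnip3 and Adm differed by 3.09 and 3.24, and Egln3 was listed at 0 in MECPK and had 9.11 ± 0.06 TPM in MSH2KO21B.

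Cytosolic ribosomal protein genes were slightly lower in MSH2KO21B, in 31 of 44 members, with Rpl11, named after its values were seen, higher, though not after median-ratio scaling, and 3 members higher after quantile normalization (median relative to all genes -0.61, camera adjusted p = 6.1e-06, and adjusted p = 0.664 with an estimated correlation). Rps15 fell from 2873 ± 112 to 1578 ± 24.2 TPM, and Rps24, Rpl12 and Rps7 by 0.77, 0.72 and 0.70 on the log2 scale. Mitochondrially encoded genes were higher in 12 of 13 members, all but mt-Co1 (median relative to all genes 0.85, adjusted p = 0.0396, and adjusted p = 0.754 with an estimated correlation), and mt-Nd2 had 999 ± 197 and 2371 ± 55.1 TPM. Their share of all TPM was 1.92% and 2.61% in the MECPK libraries, which differed from each other, and 4.26% and 4.28% in MSH2KO21B. The list's call was lost without MSH2KO21B replicate 1 (0.0728) or 2 (0.0675), as were those of mt-Nd4 (log2 difference 1.27), mt-Nd4l (1.26) and mt-Nd5 (1.15).

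Among the other lists, none was called and several had a median and a mean that differed in sign. Mismatch repair genes were higher in 14 and lower in 4 of 22 members, or 9 and 5 after quantile normalization (adjusted p = 0.537). Their median was 0.19 relative to all genes and their mean -0.13 relative to other genes. The polymerase subunit gene Pold4 was lower (98.9 ± 4.87 against 5.83 ± 0.41 TPM), and Rpa2 (1.04) and Exo1 (0.84) were higher. Homologous recombination and Fanconi anaemia genes were higher in 20 and lower in 1 of 28 members (adjusted p = 0.0545), or in 10 and 4 after quantile normalization and 13 and 2 after median-ratio scaling. Fancg (1.17), Rbbp8 (1.13) and Blm (0.98) were higher, and Rad51d was the lower member as deposited (-2.01). The call of Blm was lost without MSH2KO21B replicate 1 (0.0508) or 2 (0.0631). The unfolded protein and integrated stress response had 11 higher and 6 lower of 24 (adjusted p = 0.665), led by Vldlr (2.42), Atf3 (1.84), Dnajb9 (1.29) and Sdf2l1 (1.20). Its median was -0.02 relative to all genes and its mean 0.06 relative to other genes. NRF2 targets were higher in 9 and lower in 9 of 27 (8 and 9 adjusted over the list alone; adjusted p = 0.645), or in 8 and 12 after quantile normalization and 8 and 13 after median-ratio scaling. They had a median of -0.14 relative to all genes and a mean of 0.44 relative to other genes. The largest differences were in the glutathione transferase genes Gsta4 (2.61 ± 0.79 against 922 ± 7.61 TPM) and Gsta1 (0.97 ± 0.24 against 82.3 ± 0.06 TPM) and the quinone reductase gene Nqo1 (0.12 ± 0.02 against 14.7 ± 1.97 TPM). Gsta3 was listed at 0 in both MECPK libraries and had 5.62 ± 0.49 TPM in MSH2KO21B.

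Imprinted genes moved both ways, 6 higher and 5 lower of 12 tested (adjusted p = 0.665; median 0.31 relative to all genes, mean -0.08 against other genes). Peg3 was at 0.03 ± 0.02 TPM in MECPK and 49.5 ± 7.79 TPM in MSH2KO21B and Plagl1 at 1.19 ± 0.73 and 16.2 ± 5.24 TPM. Mest (25.3 ± 3.35 against 0.90 ± 0.03 TPM) and Snrpn (10.2 ± 0.28 against 0.05 ± 0.07 TPM) were lower. Replication-dependent histone genes had 6 higher and 5 lower members of 22 (5 and 4 adjusted over the list alone; adjusted p = 0.537), and 3 and 13 after quantile normalization. Hist1h2bc (2.56), Hist1h1c (1.78) and Hist1h4h (1.38) were higher and Hist1h1e lower (-1.18), the last call lost without MSH2KO21B replicate 1 (0.0639) or 2 (0.0744). The list's median was -0.33 relative to all genes and its mean -0.15 relative to other genes. Of 25 germline genes 1 passed the filter, Prdm9, which was higher at 1.31 ± 0.15 and 2.24 ± 0.40 TPM. Its call was lost after quantile normalization, where its sign turned, and without any of MECPK replicate 1, MECPK replicate 2 or MSH2KO21B replicate 2 (adjusted p from 0.0562 to 0.0958). Of the X and Y identity genes Uty alone passed the filter, with 14.5 ± 0.61 and 48.2 ± 6.84 TPM.

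Camera called 11 of the 27 lists, 5 higher and 6 lower. With an estimated correlation it called none, none was at an unadjusted p under 0.05, and the lowest adjusted p was 0.586. For p53 targets the estimated correlation, -0.009, was below the preset 0.01, yet camera's unadjusted p rose from 4.2e-04 to 0.0575. This version had only 2 degrees of freedom here, so the lack of calls does not by itself show that correlation between genes undoes them. Limma's fry, which asks only whether a list moves to either side, called 25. Counts adjusted over the list alone were the same as those over all genes in 25 of the 31 lists and are given beside the latter for the other 6.

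**Figure D2:**
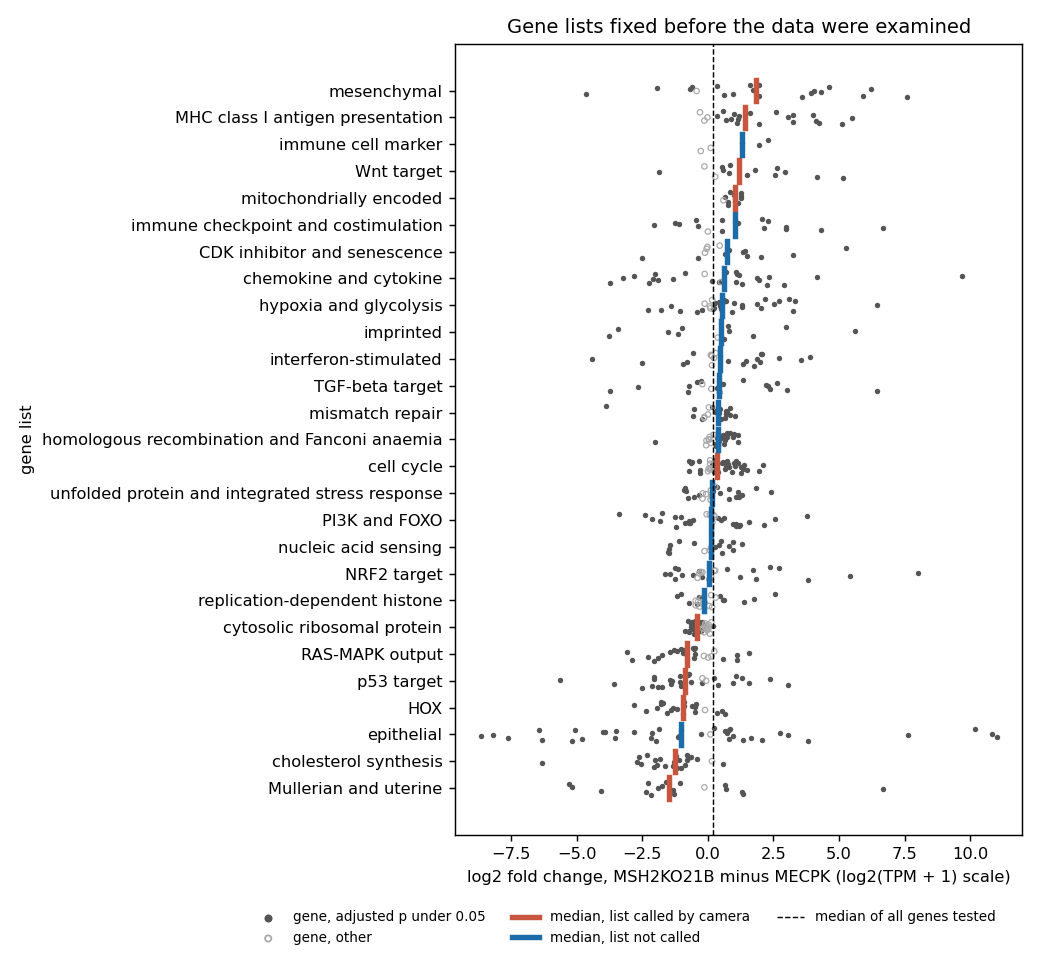
Log2 differences between the lines (horizontal axis, log2(TPM + 1) scale, MSH2KO21B minus MECPK) of the tested members of 27 gene lists (vertical axis). Filled dots are genes past an adjusted p of 0.05, open circles the others, bars list medians (red for lists called by camera, blue for the others), and the dashed line the median of all genes, 0.19. Cholesterol synthesis members lie left of that line apart from Ebp.

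The differences also followed the chromosomes, a comparison chosen after the data were seen. The 412 tested genes of chromosome 19 had a median of -0.89 relative to all genes, and 83.3% of them lay below the median of all genes (camera adjusted p = 4.2e-15 over the chromosomes, and adjusted p = 0.0969 with an estimated correlation). The 4 pairs of libraries between lines gave -0.91 to -0.88. Pold4, Pax2, Ankrd1, Dusp5, Rnaseh2c and Tm7sf2, named above as lower, and Ifit2 and Vldlr, named as higher, lie on this chromosome. Camera also called chromosomes 14, 10 and 12 lower (-0.48, -0.40 and -0.21) and chromosomes 7, 3, 18, 4, 9 and 16 higher (0.39, 0.37, 0.37, 0.30, 0.26 and 0.21). With an estimated correlation no chromosome passed the threshold, and the adjusted p of these 9 ran from 0.0969 to 0.428. As for the lists, that version of camera had few degrees of freedom and little power here.

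**Figure D3:**
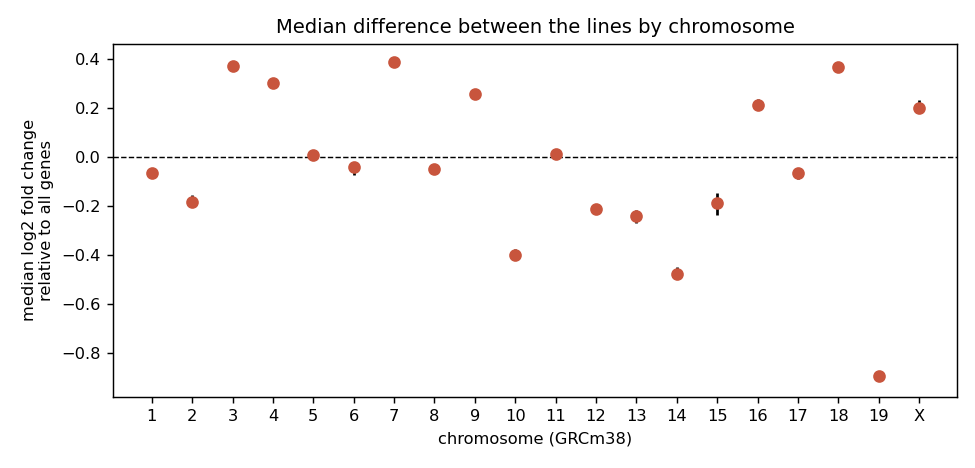
Median log2 difference between the lines for the tested genes of each chromosome (horizontal axis, GRCm38), relative to the median of all genes (vertical axis, log2 units). Dots are medians from the line means, vertical bars run over the 4 pairs of libraries between lines, and chromosome 19 lies lowest at -0.89.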

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

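Median-ratio scaling, rescaling without the mitochondrially encoded genes and the sum over protein-coding transcripts only were chosen after the results were seen; the other alternatives were planned. The number of genes called was within 1.5 times of 9088 in every alternative fit, from 6613 with a filter of 10 TPM, where 8524 genes were tested, to 10052 with no filter, except for treat, which asks for a difference over 1 and called 2443. Without MSH2KO21B replicate 2 it was 7044. Genes differing by over 1 numbered 2244 with the filter of 10 TPM. In fits that left out a library, the lone library of its line was assumed to vary like the other line.

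The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at r = 0.016 across genes. With the replicate block 9113 genes were called, 8872 of them among the 9088, and the cell cycle list was no longer called.

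Among the 135 named genes, 18 combinations of a gene and an alternative ended a call, 1706 did not, and Prdm9 alone turned sign, to -0.0672 after quantile normalization. Lists called numbered 0 with an estimated correlation and 25 by fry, which does not compare a list with other genes. Of the 11 lists called, 8 were called under every alternative other than the estimated correlation. Directions given by the test statistics, which need not match the sign of a mean, turned for 5 lists that camera had not called. Camera's turned for immune cell markers with no filter, though their mean difference stayed positive (0.0829, against 0.826 in the main fit). It also turned for the unfolded protein response without MECPK replicate 2 (-0.0341, against up to 0.162 with other libraries left out). Fry gave a higher direction, where camera gave a lower one, for PI3K and FOXO (list mean -0.0239), NRF2 targets (0.689) and histones (0.10003). Camera's mean differences for the first 2 of these, -0.28 and 0.44, had the same signs as the list means. The cause was not tested. Lists were not run without the trend or with a filter of 10 TPM. TPM keeps no depth, so the limit that depth sets is unknown.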

Other observations

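Apart from the removal of a trend over GC content and length and the test of chromosome-wide shifts, the tests and gene lists in this part were chosen only after the results were seen. Genes of stratified, cornifying epithelium formed a group outside the planned lists: of 35 such genes 32 passed the filter, 30 were higher in MSH2KO21B and Ppl alone was lower (limma, adjusted over all genes). Desmosomal cadherins of skin and other stratified epithelia were among them, with Dsg3 at 0.10 ± 0.01 TPM in MECPK and 189 ± 0.80 TPM in MSH2KO21B (SD, n = 2) and Dsc3 at 0.03 and 135 ± 1.07 TPM. Dsg1a and Dsc1 were listed at 0 in both MECPK libraries and stayed low in MSH2KO21B, at 4.84 ± 0.34 and 3.66 ± 0.14 TPM. The hemidesmosome collagen gene Col17a1 was at 0.18 ± 0.01 and 676 ± 6.33 TPM, and Pitx1, a transcription factor of the hindlimb and oral region, at 0.16 ± 0.08 and 188 ± 10.98 TPM. Some products of the cornified layer were present in MSH2KO21B, with Sbsn at 326 ± 3.30, Flg at 40.1 ± 5.85 and Sprr1b at 61.4 ± 0.62 TPM. Flg and Sprr1b were listed at 0 in both MECPK libraries. Others were low in MSH2KO21B, with means of 8.58 TPM for Lor, 6.31 for Ivl, 0.70 for Tgm3 and 0.68 for Sprr3. All 5 simple keratins were lower, including Krt8 (1517 ± 20.8 against 44.7 ± 1.66 TPM) and Krt19 (663 ± 7.95 against 7.29 ± 0.56 TPM). These counts were the same after median-ratio scaling, and after quantile normalization 29 genes were higher. Of 20 housekeeping genes 6 were higher and 6 lower, and none was at 0 in any library.

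Of the posterior HOX genes, Hoxa9, Hoxa10, Hoxa11 and Hoxd13 were listed at 0 in all 4 libraries, as was the progesterone receptor gene Pgr. Hoxa13 was at most 0.22 TPM, whereas Hoxd9 had means of 16.4 TPM in MECPK and 4.05 TPM in MSH2KO21B. Hmga1b and Hmga1 are near-copies that share reads, and both were lower in MSH2KO21B, with Hmga1b at 9755 ± 988 TPM in MECPK and 1147 ± 8.87 TPM in MSH2KO21B and Hmga1 at 2659 ± 265 and 327 ± 13.1 TPM. The Y-linked genes Kdm5d and Eif2s3y were listed at 0 in all 4 libraries and Ddx3y was at most 0.013 TPM. Uty, which has an X-linked homologue, had 14.1, 14.9, 43.3 and 52.99 TPM, all from 1 transcript. The transcript ENSMUST00000090860.6, which had no match in the annotation used, had 1203 and 1155 TPM in MECPK and 6.06 and 1.71 TPM in MSH2KO21B, and was among 27 unmatched transcripts that reached 100 TPM in a library.

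The lower values across chromosome 19 (median -0.89 relative to all genes, 412 genes) were weighed first. A trend over GC content and transcript length took 0.101% of the variance of the differences, so removing it moved little, and the median was then -0.8979. It was argued against as the cause because genes off this chromosome, in 10 groups by GC content, had medians from -0.0212 to 0.0794 relative to all genes, and in 10 groups by length from -0.0225 to 0.0850. A small number of genes with very large differences would leave most genes in place, whereas 83.25% of the genes lay below the median of all genes. That share is part of the pattern itself and not a separate test. A difference in copies of the chromosome between the lines is a candidate explanation. All 5 position bins were lower, from -1.04 in the first to -0.7953 in the last and least shifted, from 45552275 to 61297069. The shift was therefore not confined to 1 part of the chromosome. Low bins were likely once 83.25% of the genes lay below the median, so they are not a separate test either. DNA was not analysed here, so which line may have gained or lost copies, and whether other differences between the lines contribute, stays open.

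The higher MHC class I genes in MSH2KO21B were weighed next. Immune cells in the cultures were argued against, because the highest value of Ptprc, Tyrobp, Cd74 and Laptm5 there was 0.307 TPM. The planned immune cell markers S100a9, Csf1r and Coro1a went the other way, with means of 3.94, 3.41 and 3.18 TPM in MSH2KO21B. An H2 haplotype unlike the reference could lower the estimates of heavy chain genes in either line, and their median of 1.488 relative to all genes cannot be told apart from such an effect without reads. That haplotype effect was not weighed for Tap1 and Psmb8, which also lie on chromosome 17 (log2 differences 3.07 and 5.10). It would leave the genes outside the H2 region in place, yet B2m was 2.389 above the median of all genes (SE 0.06) and Nlrc5 further. Among 10 members outside chromosome 17, 7 were higher with a median of 0.54 over the 10 relative to all genes, below the 1.21 of the list, and a difference in regulation between the lines may account for them, which no test here addressed.

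The lower p53 targets were weighed last. Chromosome-wide shifts were argued against, because the list median was -1.322 after each gene's chromosome median was subtracted, and GC content and length because the trend over them predicted no gene lower than -0.0959 relative to its median. Removing that trend moved little and left the list at -0.9939. Lower p53 activity in MSH2KO21B, through p53 itself or less upstream stress, is a candidate explanation, with 19 of 29 targets lower and 8 higher. These routes cannot be told apart, because RNA levels show neither p53 protein nor damage. Whether other differences between the lines contribute stays open. Mdm2 was among the lower targets, at 126 ± 3.31 TPM in MECPK and 29.7 ± 0.82 TPM in MSH2KO21B. Perp was among the higher, with means of 214 and 1101 TPM.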
